A study of Homo sapiens with 19 samples.

How the data were processed

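Chromatin of MDA-MB-231 and MDA-MB-436 derivatives was precipitated with 5 µg of antibody against H3K27ac or OCT-2, and libraries were amplified with 15 PCR cycles, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.2.6, Bowtie, HOMER and bedtools and the builds hg19 and hg38, without roles or thresholds; how superenhancers and peaks were called and what was subtracted is not given in the sources used here. The deposited files are 10 lists of genomic intervals with start, end and a text name that holds the centre and the number of merged calls. They carry no counts, scores or signal and no value per replicate, so the authors' lists were used as they stand. No comparison of depth, height or replicate agreement was possible, and p-values measure the spread between regions or genes. In the lists of the common and the transgenic cells every region is a merge of 2 or more calls, and in the specific lists every name holds 1. Whether the replicates come from separate cultures is not given in the sources used here.

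The 3 lists of 231Pa and 231-D superenhancers and the OCT-2 peaks of 231-D are in hg19, and the lists of 231Pa_Luc+GFP, 231Pa_Luc+OCT-2 and the OCT-2 peaks of 231Pa_Luc+OCT-2 in hg38, per the names the authors gave them. The build of the 3 MDA-MB-436 lists was settled from region ends. No coordinates were converted. 5 OCT-2 peaks on unplaced contigs, of 5741, were left out. Coordinates are printed 1-based. Gene positions came from a RefSeq table of GRCh38.p14 with 59094 genes, of which 19970 are protein-coding; it gives neither strand nor exons. Both gene ends therefore stand in for promoters, the nearest gene is taken by the gene body, and genes were assigned for the 3 hg38 lists alone. Where a region overlapped several genes, the nearest was the one whose middle lay closest to the middle of the region. All 231 distinct genes of the 15 fixed lists were matched, 1 of them through an older symbol.

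Regions of 231Pa_Luc+OCT-2 and 231Pa_Luc+GFP were called shared with an overlap of 1 bp or more. Class shares were compared with two-sided Fisher exact tests, also within 4 width strata (Mantel-Haenszel odds ratio, class labels permuted 100000 times within strata). Differences of median width were tested with 100000 permutations, with bootstrap intervals from 2000 samples. Chromosome distributions were tested by permuting class labels 100000 times; the smallest p that these permutations can give is 1.0e-05. Random placement put each region 1000 times within the span of its chromosome (one-sided p, smallest 0.0010), and the spans came from the lists and, for hg38, the gene table, so sequence gaps were not left out. Open chromatin outside the lists was not known, so random placement is a generous comparison. A gene list was tested per class by a Fisher exact test of its protein-coding members, gene body extended by 10 kb, against all other protein-coding genes, and for OCT-2 peaks against 10000 sets of genes matched on length. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05. Odds ratios have Woolf 95% intervals.

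The genes named are the nearest genes of the 10 widest regions per class (the lists hold no score), members of the fixed lists at superenhancers or with OCT-2 peaks, and POU2F2; a few genes that the rule takes are not reported here. Gene lists, most tests and most alternatives were fixed before the data were examined; the comparison of superenhancers between the lines by position, with its tests, and some further tests were chosen afterwards. The motif test planned for OCT-2 peaks, gene-based comparisons between the lines and between both OCT-2 lists, and alternatives based on scores were not run, because no genome sequence, no hg19 gene table and no score were used here. Region overlap in hg19 replaced the comparison of genes between the lines.

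The statistics were tested on simulated data. Placement of 204 unrelated regions gave p under 0.05 in 4.5% of 400 runs. Regions placed at random over genes gave gene list calls in 0.067% of 4500 adjusted tests, and lists with 5 members planted at Luc+OCT-2-only regions were called in 100% of 50 runs. Width permutation called 4.5% of 200 pairs without a difference. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.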

Results

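The data describe superenhancers, broad regions of dense H3K27 acetylation, and the binding of OCT-2 (the octamer-binding transcription factor encoded by POU2F2, best known from B lymphocytes) in human triple-negative breast cancer cells. Of the 19 ChIP-seq samples, 12 were precipitated with an antibody against H3K27ac, 4 with an antibody against OCT-2, and 3 were inputs. Cells were profiled for H3K27ac in pairs, with 2 replicates for each member of a pair. The first pair was the parental MDA-MB-231 line (231Pa) and 231-D, a clone of high metastatic ability derived from it. The second was 231Pa carrying luciferase and GFP (231Pa_Luc+GFP) and 231Pa carrying luciferase and forced OCT-2 (231Pa_Luc+OCT-2). The third was luciferase-marked MDA-MB-436 cells (MDA-MB-436_Luc2) and MDA-MB-436_Luc2_No3a, a culture grown out of its xenograft. OCT-2 was precipitated in 231-D and in 231Pa_Luc+OCT-2, with 2 replicates each, and no OCT-2 ChIP of 231Pa or 231Pa_Luc+GFP was analysed here. The values are 10 lists of regions made by the authors from their replicates: 8 lists of superenhancers and 2 lists of OCT-2 peaks. They hold positions without read counts, so the depth is unknown. The units of every test are therefore regions or genes, and the spread between replicate libraries does not enter any p-value. Intervals are exact (Clopper-Pearson) 95% intervals of a share and cover counting error only.

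The first comparison asks how far forced OCT-2 changed the superenhancers of the parental cells. Most of the control set was kept, and the OCT-2 cells had many additional regions. In 231Pa_Luc+OCT-2, 518 superenhancers covered 50.4 Mb, and in 231Pa_Luc+GFP 337 covered 40.3 Mb. Of the 337 control regions, 308 (91.4%, interval 87.9 to 94.2%) overlapped a region of the OCT-2 cells by 1 bp or more. Random placement within chromosomes gave a mean of 16.1 ± 3.75 (SD over 1000 placements), 19.2 times fewer, with p = 0.0010, the smallest that this permutation of positions can give (one-sided). From the other side, 314 of 518 superenhancers of the OCT-2 cells (60.6%, interval 56.3 to 64.9%) were shared and 204 were present only in the OCT-2 list, against 29 present only in the control list. The 204 regions of the OCT-2 cells alone (Luc+OCT-2-only) had a median width of 73.0 kb, against 94.0 kb for the shared ones, a difference of -21.0 kb (bootstrap 95% interval -32.7 to -9.35; two-sided permutation test, adjusted p = 4.5e-05). How many regions a list holds depends on the authors' calling threshold, and with only the 337 widest OCT-2 regions, a setting chosen after the lists were seen, the shared part of the control list was 68.2%.

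Genes of inflammatory signalling, of TGF-β signalling and, as also at shared superenhancers, of the Hippo pathway lay at superenhancers present in the OCT-2 cells alone. Of 22 genes fixed as NF-κB targets and inflammatory cytokines, 6 (27.3%) had their gene body, extended by 10 kb, at such a region, against 1.90% of all other protein-coding genes (odds ratio 19.3, 95% interval 7.52 to 49.6, two-sided Fisher exact test, adjusted p = 1.3e-04 over 45 tests). They were the interleukin-1 genes IL1A and IL1B, which share a region of 104 kb (hg38 chromosome 2, 112737325 to 112840980), the chemokine genes CXCL8 (chromosome 4, 73702351 to 73743025) and CXCL2 (chromosome 4, 74095929 to 74159463), the apoptosis inhibitor BIRC3 (chromosome 11, 102219966 to 102349793) and NFKBIZ, an atypical IκB protein (chromosome 3, 101826004 to 101964674). Of these 5 regions, 4 held OCT-2 peaks, 5 of them at BIRC3, and that of CXCL8 held none. Over all Luc+OCT-2-only regions, 73.0% held a peak. Within 10 kb of the gene itself, BIRC3 had 3 peaks, and IL1A, IL1B, CXCL2, CXCL8 and NFKBIZ had 0. Another 3 of the 22, NFKBIA, LIF and IRF1, lay at shared superenhancers (13.6%, Fisher exact test, adjusted p = 0.21).

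Of 21 genes of TGF-β and BMP signalling, 5 (23.8%) lay at Luc+OCT-2-only regions (odds ratio 16, interval 5.85 to 44.0, Fisher exact test, adjusted p = 6.2e-04). These were the type II receptor gene TGFBR2 (chromosome 3, 30577162 to 30693792, 117 kb), the genes of the SMAD co-repressors SKI (chromosome 1, 2188933 to 2256846) and TGIF1 (chromosome 18, 3446233 to 3467233), the BMP target ID1 (chromosome 20, 31514188 to 31613092) and LTBP2 (chromosome 14, 74566293 to 74623281), which encodes a protein of the latent TGF-β binding family. SMAD3 was the only member at a shared region. Of 14 YAP and TEAD genes, 3 (21.4%, Fisher exact test, adjusted p = 0.014) lay at Luc+OCT-2-only regions: YAP1, WWTR1 (which encodes TAZ) and CRIM1. At shared regions the same list gave 4 of 14 (28.6%), with CRIM1 in both classes. YAP1 and BIRC3 are neighbours and met the same region of 130 kb, in which 5 OCT-2 peaks lay. Some memberships depend on how genes were assigned. By the nearest gene alone, YAP and TEAD kept CRIM1 and WWTR1 (2 of 14, Fisher exact test, adjusted p = 0.041). TGF-β and BMP kept LTBP2, TGFBR2 and TGIF1 (3 of 21, Fisher exact test, adjusted p = 0.0084), and the NF-κB list kept 5 of 22, without IL1B (Fisher exact test, adjusted p = 9.3e-05). With only the 337 widest OCT-2 regions, only the NF-κB list stayed past the threshold in this class (4 of 22, Fisher exact test, adjusted p = 0.0039); TGF-β and BMP kept 2 of 21 (adjusted p = 0.13) and YAP and TEAD 2 of 14 (adjusted p = 0.087).

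Superenhancers shared by the OCT-2 and the control cells lay at genes of the AP-1, cell cycle, mesenchymal, YAP and TEAD, and basal lists, of which the first 2 held when fewer regions were taken. Of 24 mesenchymal genes, 6 (25%) met a shared region (odds ratio 8.30, interval 3.29 to 21.0, Fisher exact test, adjusted p = 0.0028): VIM, CD44, AXL, ITGB1, MMP14 and S100A4. Of 11 AP-1 genes, 5 (45.5%) did so (odds ratio 20.7, Fisher exact test, adjusted p = 6.2e-04), namely FOSL1, FOSL2, FOSB, JUND and MAFF, while JUN lay at a Luc+OCT-2-only region. By the nearest gene, or with gene bodies extended by 50 kb, JUN counted at a shared region too. Cell cycle and oncogenes gave 5 of 17 (29.4%, Fisher exact test, adjusted p = 0.0033: BCL2L1, ETS1, MCL1, RUNX1 and RUNX2) and YAP and TEAD 4 of 14 (28.6%, adjusted p = 0.012: AJUBA, AMOTL2, CCN1 and CRIM1, whose long gene body meets regions of both classes). The basal list gave 4 of 18 (22.2%, Fisher exact test, adjusted p = 0.025), among them EGFR, ITGB4 and LAMB3. This list did not pass the threshold in a permutation against random lists matched on gene length (adjusted p = 0.056) or with gene bodies extended by 50 kb (adjusted p = 0.078). With only the 337 widest OCT-2 regions, AP-1 (4 of 11, Fisher exact test, adjusted p = 0.0049) and the cell cycle list (5 of 17, 0.0039) stayed past the threshold, while mesenchymal genes (4 of 24, Fisher exact test, adjusted p = 0.068), basal genes (3 of 18, 0.11) and YAP and TEAD (2 of 14, 0.25) did not. At the Luc+OCT-2-only regions the mesenchymal and epithelial lists had no member, the basal list gave 1 (ITGA6), the cell cycle list 1 (CCND3), the list of genes known from metastasis of MDA-MB-231 1 (ID1, Fisher exact test, adjusted p = 1.0) and the hypoxia list 2 of 13 (ADM and HK2, adjusted p = 0.13). At the shared regions the metastasis list gave 3 of 26 (COL13A1, HBEGF and KRT81, Fisher exact test, adjusted p = 0.29), hypoxia 2 of 13 (LOXL2 and SLC2A1, adjusted p = 0.31) and the epithelial list 1 of 19 (KRT7). Markers of leukocytes and of neural or melanoma cells and the B-cell genes known as OCT-2 targets had no member at any of the 3 classes, and the only gene of any list at a region of the control cells alone was the endothelial marker PECAM1 (1 of 12, Fisher exact test, adjusted p = 0.13). The share of each list was not shown to differ between Luc+OCT-2-only and shared regions: tested directly on the genes of each class, with genes that met both classes counted as shared, TGF-β and BMP gave 5 of 375 against 1 of 776 genes (Fisher exact test, p = 0.016, adjusted p = 0.24 over 15 lists) and NF-κB 6 of 375 against 3 of 776 (p = 0.066, adjusted p = 0.49), while YAP and TEAD gave 2 of 375 against 4 of 776 (odds ratio 1.03, Fisher exact test, p = 1.0).

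**Figure D1:**
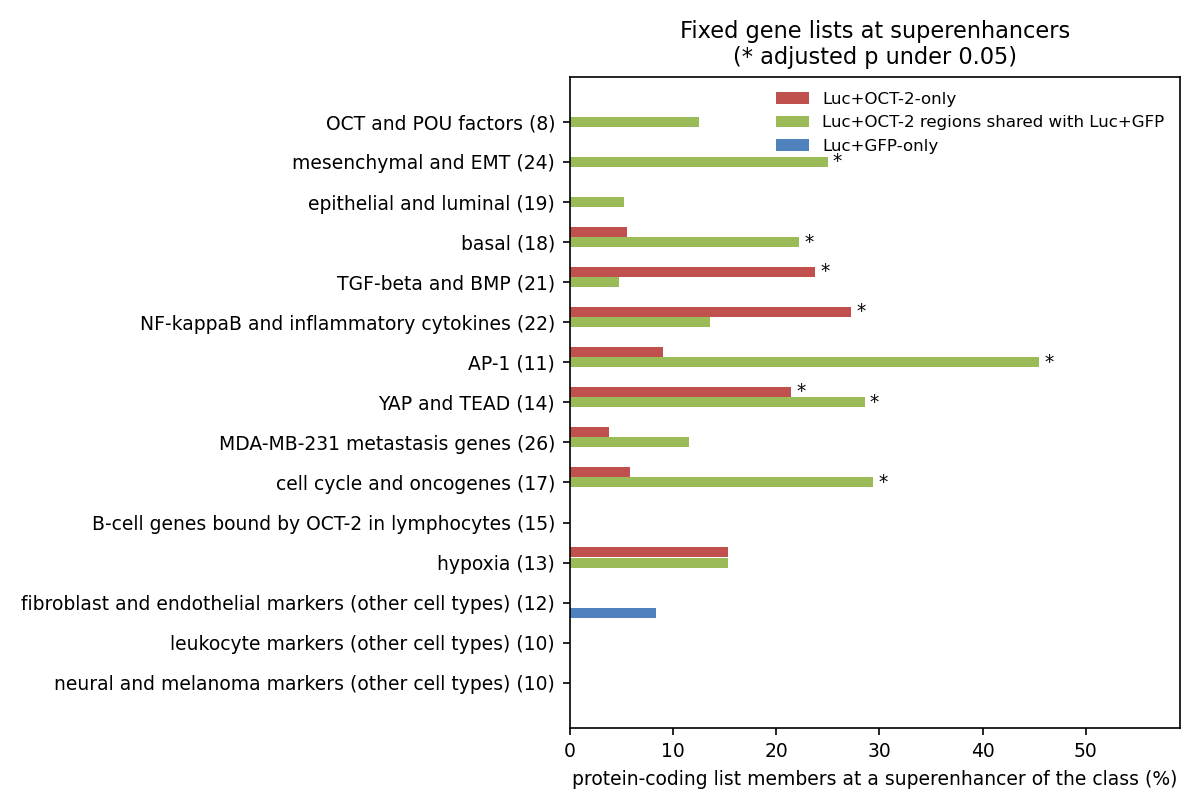
The bars give the percent of protein-coding members of each fixed gene list (number of members in parentheses) whose gene body extended by 10 kb met a superenhancer present in the OCT-2 cells alone, shared with the control cells, or present in the control cells alone. Asterisks mark an adjusted p under 0.05 (Fisher exact test), reached by NF-κB (27.3%), TGF-β and BMP (23.8%) and YAP and TEAD (21.4%) in the first class and by 5 lists in the shared class.

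The gene of OCT-2 itself, POU2F2 (hg38 chromosome 19, 42086110 to 42197936), the only one of 8 genes of POU factors and their coactivator at a superenhancer of these cells, overlapped a superenhancer in both cell populations, of 58.9 kb in the OCT-2 cells and 58.8 kb in the control cells, with 0 OCT-2 peaks within 50 kb of the gene. The widest Luc+OCT-2-only region (231 kb, chromosome 20, 50220426 to 50451849) overlapped no protein-coding gene and was nearest to CEBPB, the gene of a transcription factor of inflammatory responses, at 27.7 kb. Among the next widest were regions at ARHGAP35, the chloride channel gene ANO1, TM4SF18, GTF2F2, an uncharacterised gene on chromosome 19, RAB31 and LYPD6B, and 1 region on chromosome 10 was 271 kb from any protein-coding gene. The widest shared region (471 kb) was nearest to SLC45A1 and held 11 OCT-2 peaks. The next widest were nearest to UGCG, EXT1, ISYNA1, MICAL2, AJUBA, DUSP4, TTC7A, ERGIC1 and FRMD4A. Many of these regions overlapped more than the gene named, with 4 genes at that of SLC45A1, 14 at ISYNA1 and 16 at AJUBA. Of the 29 regions of the control cells alone, the widest lay at BDH1 (226 kb), ARNT2, LGALS2, RIPK4, near ZNF703, and at ROR1, PECAM1, PDP1, CALM2 and SAMD4A.

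**Figure D2:**
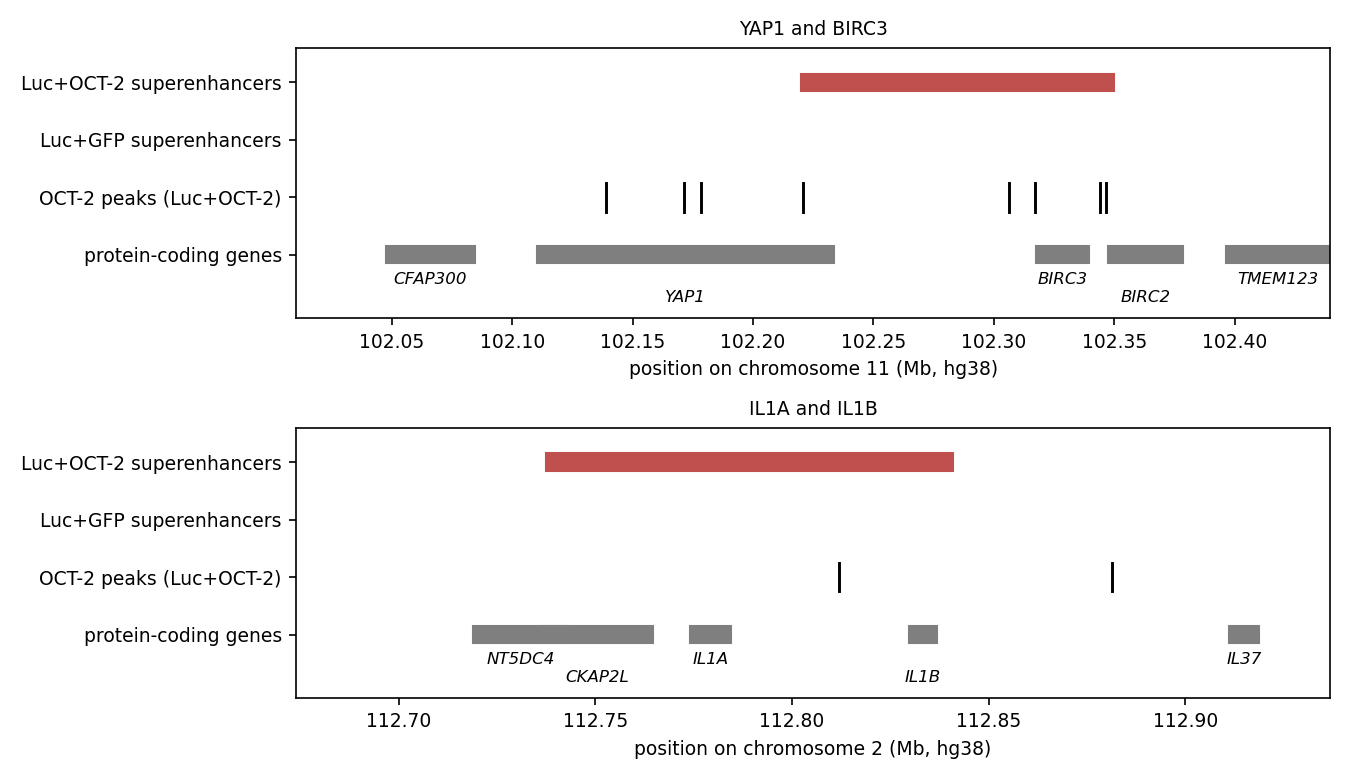
The maps show the YAP1 and BIRC3 locus on chromosome 11 and the IL1A and IL1B locus on chromosome 2 (positions in Mb, hg38), with superenhancers of 231Pa_Luc+OCT-2, superenhancers of 231Pa_Luc+GFP, OCT-2 peaks and protein-coding genes in separate rows. Each locus holds a superenhancer of the OCT-2 cells and none of the control cells; 5 OCT-2 peaks lie inside the first region and 1 inside the second.

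OCT-2 binding in the OCT-2 cells was next set against these superenhancers. OCT-2 peaks lay in most superenhancers of these cells, including those shared with the control cells; forced and endogenous OCT-2 cannot be told apart here. At least 1 of the 5736 OCT-2 peaks lay in 406 of 518 superenhancers of the OCT-2 cells (78.4%, interval 74.6 to 81.8%), against a mean of 80.3 ± 8.29 regions with random placement, 5.05 times fewer (permutation of positions, p = 0.0010). With placement over the ends of protein-coding genes the ratio was 3.69 (permutation of positions, p = 0.0010). Neither placement took open chromatin into account, so a preference of OCT-2 for superenhancers over other open chromatin cannot be read from these ratios. The density inside them was 17.9 peaks per Mb, against 1.89 per Mb over the genome, although only 15.8% of all peaks lay there. The share with a peak was 73.0% (149 of 204) for Luc+OCT-2-only regions, 81.8% (257 of 314) for shared regions and 79.3% (23 of 29) for regions of the control cells alone. The difference between the first 2 classes did not pass the threshold after adjustment (odds ratio 0.60, interval 0.39 to 0.92, two-sided Fisher exact test, p = 0.022, adjusted p = 0.065). The first class is narrower, and within width quartiles the odds ratio was 0.82 (permutation p = 0.42). Luc+OCT-2-only and control-only regions were not shown to differ (odds ratio 0.71, interval 0.27 to 1.83, Fisher exact test, adjusted p = 0.81).

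Among the 15 lists, YAP and TEAD genes had the highest share with a peak within 10 kb, 11 of 14, among them YAP1, WWTR1, TEAD1, TEAD4, CCN2 and AMOTL2. Gene sets matched on length had a mean of 3.30 ± 1.48 (SD), 3.34 times fewer (permutation of list membership within length deciles, adjusted p = 0.0030 over 15 lists). These sets were matched on length alone, so genes silent in these cells could enter them. Of the YAP and TEAD genes with a peak, AJUBA, AMOTL2, CRIM1, WWTR1 and YAP1 lay at superenhancers, where peaks were dense. Cell cycle and oncogenes had a peak at 11 of 17 (3.17 times the matched mean, permutation test, adjusted p = 0.0030), among them MYC, MET and CDK6, and TGF-β and BMP genes at 10 of 21 (3.00 times, adjusted p = 0.0040), among them TGFBR2, SMAD7 and TGFB2. By the same permutation, the mesenchymal list had 8 of 24 (adjusted p = 0.12), the list of POU factors and coactivator 4 of 8 (adjusted p = 0.12), the metastasis list 9 of 26 (adjusted p = 0.083) and the basal list 6 of 18 (adjusted p = 0.25). NF-κB genes had 4 of 22 (2.0 times, permutation test, adjusted p = 0.51), the epithelial list 4 of 19 (adjusted p = 0.81), AP-1 2 of 11 (adjusted p = 0.81) and hypoxia 3 of 13 (adjusted p = 0.81). The B-cell list had 2 of 15, CD36 and PAX5, at 0.95 times the matched mean (permutation test, adjusted p = 1.0). The lists of other cell types gave 2 of 12 fibroblast and endothelial, 2 of 10 leukocyte and 1 of 10 neural and melanoma markers (adjusted p of 0.91 to 1.0).

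Histone and small nuclear RNA genes, which include textbook carriers of octamer elements, often had an OCT-2 peak nearby. The octamer itself was not looked for in the peaks. Within 1 kb of an end of the gene, 23 of 74 histone genes (31.1%, interval 20.8 to 42.9%) had an OCT-2 peak, against 2.92% of protein-coding genes (odds ratio 15.6, interval 9.45 to 25.7, Fisher exact test, p = 6.7e-18). Because histone genes lie close together, 17 peaks stand behind the 23 genes. Small nuclear RNA genes had a peak at 14 of 20 (70.0%, interval 45.7 to 88.1%), among them RN7SK, RNU4-1, RNU4-2, RNU5A-1 and RNU6-1. The H2B genes, whose promoters are the classical octamer carriers, gave 7 of 19, and other histone genes gave 16 of 55 (odds ratio 1.42, interval 0.47 to 4.27, Fisher exact test, p = 0.57). Both groups shared peaks, with 8 near H2B genes, 16 near other histone genes and 17 in all. The test takes the groups as independent, so it cannot tell whether H2B genes differ. Over all peaks, 8.75% lay within 1 kb of an end of a protein-coding gene, 45.4% elsewhere in a gene body and 45.9% outside genes.

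The comparison of 231-D with 231Pa asks which superenhancers the metastatic clone and its parent have apart. Specific and common regions were present in similar numbers. The 225 regions listed for 231-D alone were 55.1% of the 408 regions listed for it alone or in common (interval 50.2 to 60%), and the 158 listed for 231Pa alone were 46.3% of 341 (interval 40.9 to 51.8%), with 183 in common. A common region merges 2 to 4 calls, so these totals count merged regions rather than the superenhancers called in each cell. The 231-D-specific regions were narrower, with a median of 76.8 kb against 101.6 kb for 231Pa-specific ones (difference -24.8 kb, interval -38.8 to -10.5, permutation test, adjusted p = 3.1e-04). Common regions had a median of 126.9 kb, but each is the union of the calls of both cells, which widens them by construction. Here and for all hg19 regions, genes are not named because the gene table used is of hg38. The widest 231-D-specific region (hg19 chromosome 14, 23290311 to 23585507, 295 kb) held no OCT-2 peak and the widest 231Pa-specific one (chromosome 1, 234905818 to 235184653, 279 kb) held 1, and each met 1 superenhancer of MDA-MB-436.

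OCT-2 peaks of 231-D lay in superenhancers of every class. The labels of these OCT-2 samples call the clone polyclonal with a stably expressed transgene and list luciferase as the only one; they call the OCT-2 endogenous, which the peaks cannot test. Of the 917 peaks, 58 were in 231-D-specific regions, 71 in common ones and 26 in 231Pa-specific ones, densities of 3.2, 2.6 and 1.5 peaks per Mb against 0.32 over the genome. A peak was present in 51 of 225 231-D-specific regions (22.7%, interval 17.4 to 28.7%), 7.97 times the mean of random placement, in 56 of 183 common regions (30.6%, 6.45 times) and in 23 of 158 231Pa-specific regions (14.6%, interval 9.46 to 21.0%, 4.48 times; permutation of positions, p = 0.0010 for each, the smallest possible). Random placement did not take open chromatin into account here either, and placement over gene ends was not run for hg19 lists. 231Pa-specific regions had a peak less often than common ones (odds ratio 0.39, interval 0.22 to 0.66, two-sided Fisher exact test, adjusted p = 0.0015). The difference between 231-D-specific and 231Pa-specific regions did not pass the threshold after adjustment (odds ratio 1.72, interval 1.00 to 2.96, p = 0.0498, adjusted p = 0.072); within width quartiles it did, with an odds ratio of 2.14 (permutation test, adjusted p = 0.019). 231-D-specific and common regions were not shown to differ (odds ratio 0.66, Fisher exact test, adjusted p = 0.072).

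**Figure D3:**
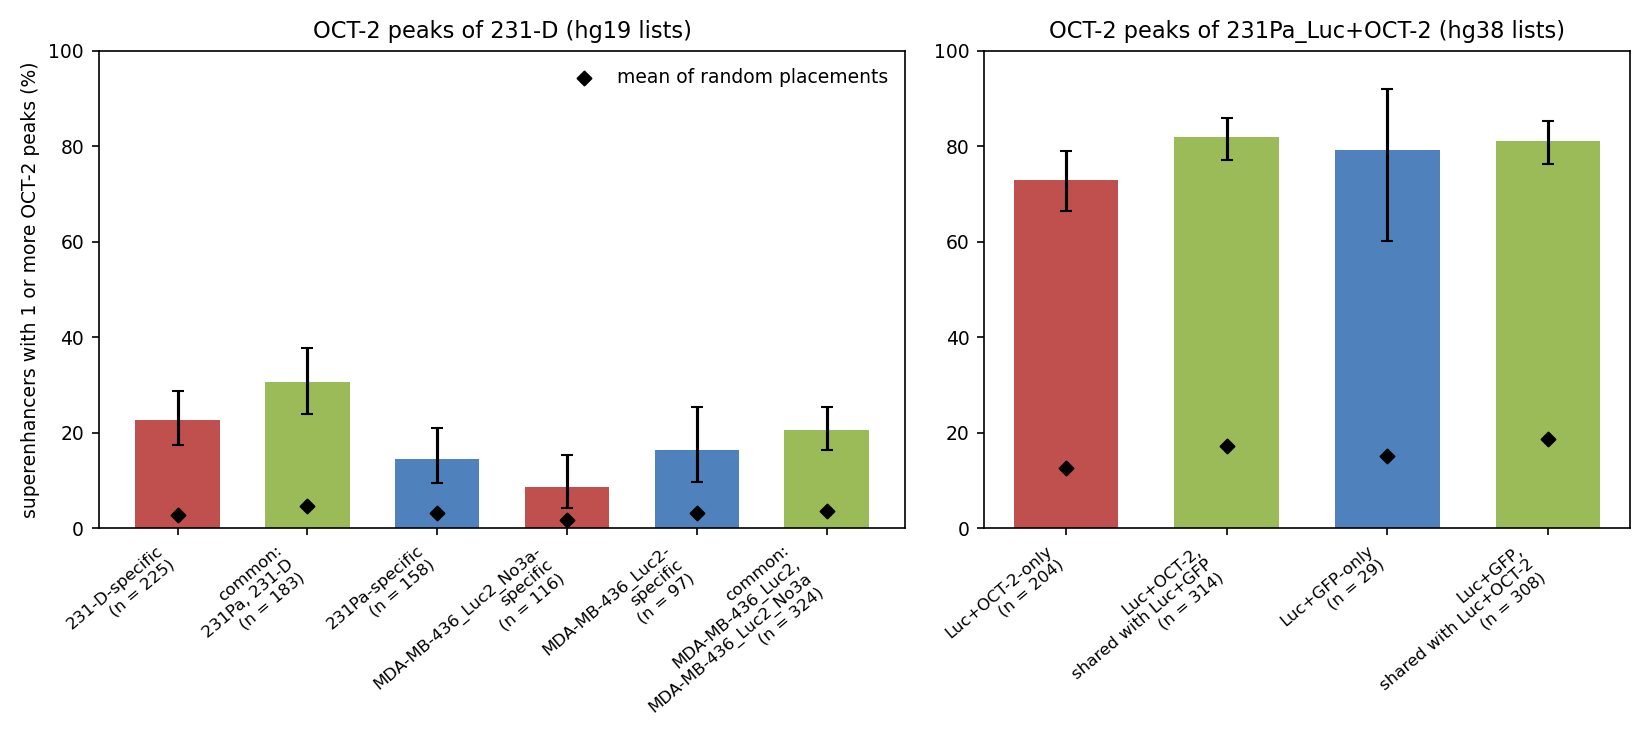
The bars give the percent of superenhancers of each class that held 1 or more OCT-2 peaks, of 231-D in the left plot and of 231Pa_Luc+OCT-2 in the right plot, with exact 95% intervals, and diamonds give the mean of 1000 random placements. All classes lie above random placement, at 8.62 to 30.6% for the 917 peaks of 231-D and at 73.0 to 81.8% for the 5736 peaks of the OCT-2 cells.

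Specific superenhancers of 231-D and 231Pa were distributed over the chromosomes in different proportions. Chromosome 5 held 27 of the 225 231-D-specific regions (12.0%) and 6 of the 158 231Pa-specific ones (3.80%), and chromosome 2 held 10 (4.44%) and 22 (13.9%). The distributions over 23 chromosomes differed (chi-square 50.0, permutation test, p = 1.8e-04, adjusted p = 0.0013 over 7 class pairs). Taken singly, chromosome 2 passed the threshold (Fisher exact test, odds ratio 0.29, interval 0.13 to 0.63, adjusted p = 0.029) and chromosome 5 did not (odds ratio 3.45, interval 1.39 to 8.58, p = 0.0050, adjusted p = 0.058). The other 6 class pairs, of all 3 cell systems, had adjusted p of 0.065 to 0.26.

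**Figure D4:**
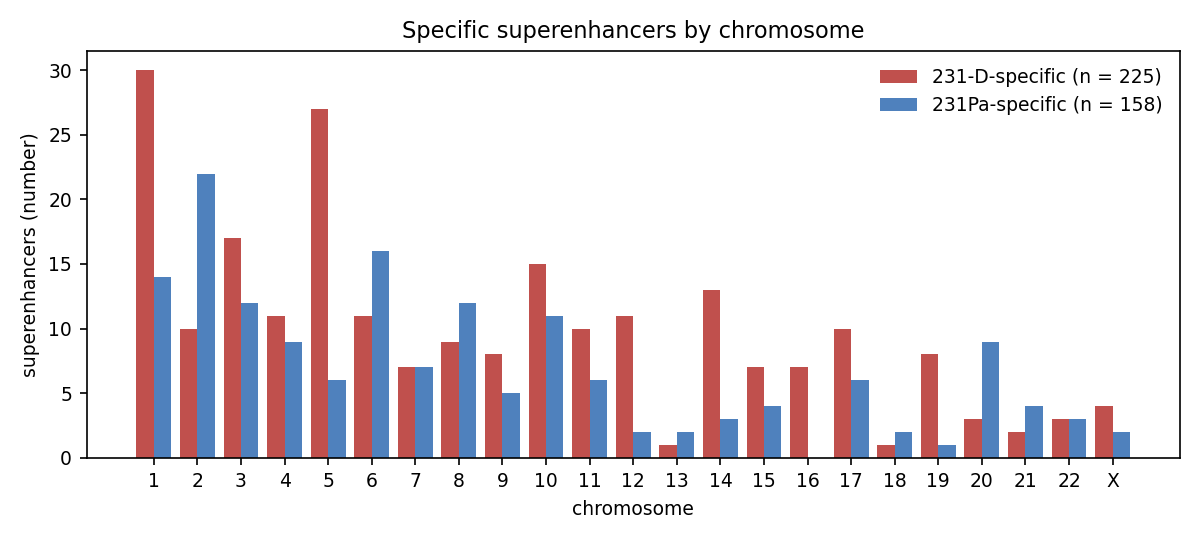
The bars give the number of 231-D-specific and 231Pa-specific superenhancers on each chromosome. Chromosome 5 held 27 against 6 and chromosome 2 held 10 against 22.

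In the MDA-MB-436 cells the xenograft-derived culture and its parent shared most superenhancers. There were 324 common regions, 116 listed for MDA-MB-436_Luc2_No3a alone (26.4% of 440 listed for it alone or in common, interval 22.3 to 30.7%) and 97 listed for MDA-MB-436_Luc2 alone (23% of 421, interval 19.1 to 27.4%). As in 231-D, the regions of the derivative were narrower than those of the parent, with medians of 48.9 and 88.6 kb (difference -39.7 kb, interval -55.5 to -24.1, permutation test, adjusted p = 3.0e-05). The labels do not tie these lists to a genome build. Of their 1074 region ends, 97 lay within 500 bp of an end in the hg19 lists of the MDA-MB-231 cells and 6 within 500 bp of an end in the hg38 lists, and they are treated here as hg19.

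On that basis the superenhancers of both lines were compared by position, in place of genes gained in more than one system. 231-D-specific regions coincided with superenhancers of MDA-MB-436 far more often than 231Pa-specific ones. An overlap was found for 91 of 225 231-D-specific regions (40.4%, interval 34.0 to 47.2%; 11 times the random mean) and for 21 of 158 231Pa-specific regions (13.3%, interval 8.42 to 19.6%; 3.45 times), with an odds ratio of 4.43 (interval 2.61 to 7.53, two-sided Fisher exact test, adjusted p = 1.0e-08 over 6 pairs). Common regions of 231Pa and 231-D overlapped in 104 of 183 cases (56.8%). 231-D-specific regions did so less often than common ones (odds ratio 0.52, interval 0.35 to 0.77, Fisher exact test, adjusted p = 0.0012). Within width quartiles the odds ratio was 0.64 (permutation p = 0.047). Of the 231-D-specific regions, 74 (32.9%) met superenhancers that both MDA-MB-436 cultures share, 10 (4.44%) met regions specific to MDA-MB-436_Luc2_No3a (8.12 times the random mean) and 8 (3.56%) met regions specific to MDA-MB-436_Luc2 (5.46 times). Of the 231Pa-specific regions, 12 (7.59%), 3 (1.90%, 2.91 times) and 6 (3.80%, 5.11 times) did so. The contrast thus lay mainly in the superenhancers that both MDA-MB-436 cultures share. Seen from MDA-MB-436, 10 of 116 MDA-MB-436_Luc2_No3a-specific regions (8.62%) and 8 of 97 specific to MDA-MB-436_Luc2 (8.25%) met a 231-D-specific one, a difference that was not tested. In the opposite direction, MDA-MB-436_Luc2_No3a-specific regions met a superenhancer of the MDA-MB-231 cells in 25 of 116 cases (21.6%) and those specific to MDA-MB-436_Luc2 in 29 of 97 (29.9%), which were not shown to differ (odds ratio 0.64, interval 0.35 to 1.2, Fisher exact test, p = 0.21). This comparison was chosen after the lists were seen.

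**Figure D5:**
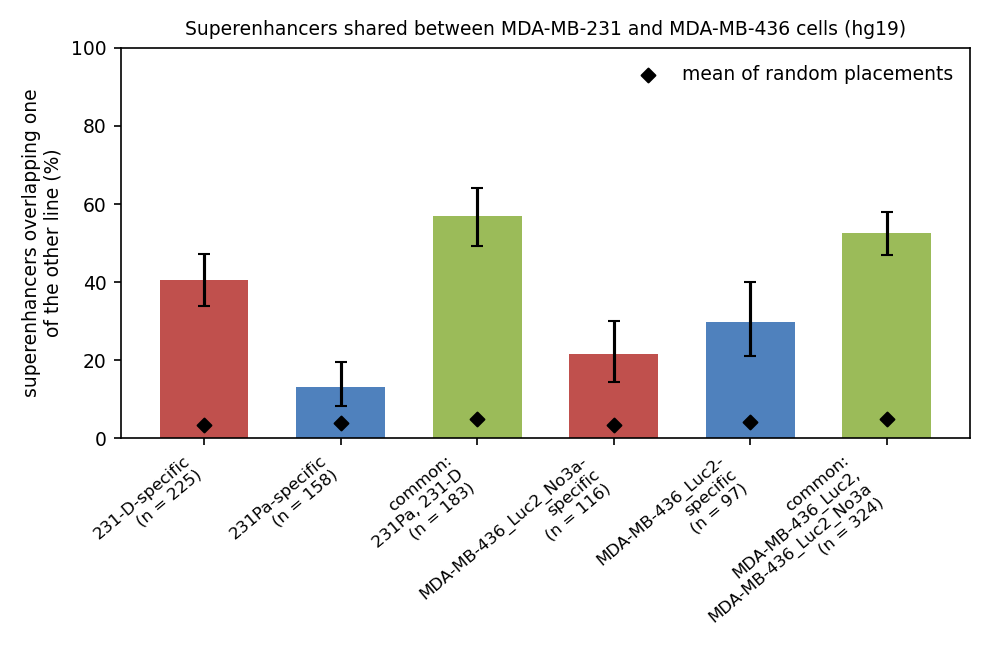
The bars give the percent of superenhancers of each class that overlapped a superenhancer of the other cell line by 1 bp or more, with exact 95% intervals, and diamonds give the mean of 1000 random placements. 231-D-specific regions reach 40.4% and 231Pa-specific ones 13.3%.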

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

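The tests of the difference between lines, of width, of random placement, of Luc+OCT-2-only against shared regions and of chromosome copies were chosen after results they bear on had been seen; the tests within chromosomes, of neighbouring genes, of the longer list and of clustered regions were set out before their results.

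The contrast between derivative-specific and parent-specific regions differed in size between the MDA-MB-231 and the MDA-MB-436 cells, without a shown direction in MDA-MB-436. For meeting a superenhancer of the other line, the odds ratio of derivative-specific against parent-specific regions was 4.35 in MDA-MB-231 and 0.65 in MDA-MB-436 (0.5 added to each cell), a ratio of odds ratios of 6.72 (exact test of equal odds ratios, adjusted p = 9.5e-06 over 2 tests). Both odds ratios count overlaps between the same lists, seen from either line, so they are not independent, and the test does not allow for that. For holding an OCT-2 peak of 231-D, the odds ratios were 1.70 and 0.49, a ratio of 3.49 (exact test, adjusted p = 0.014). Taken alone, the MDA-MB-436 contrasts did not pass the threshold (Fisher exact test, p = 0.21 for the other line and adjusted p = 0.14 for OCT-2 peaks, with an odds ratio of 0.63 and a permutation p = 0.36 within width quartiles), nor did the OCT-2 contrast in MDA-MB-231 (Fisher exact test, adjusted p = 0.072), which passed it within width quartiles (odds ratio 2.14, permutation test, adjusted p = 0.019). Width was not taken out of the test of equal odds ratios. The peaks come from 231-D, and no OCT-2 peaks of the MDA-MB-436 cells were analysed here.

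OCT-2 peaks of 231-D also lay in MDA-MB-436 superenhancers that were absent from the lists of 231Pa and 231-D. Of 313 MDA-MB-436 superenhancers that met no superenhancer of 231Pa or 231-D, 38 (12.1%) held a peak, 4.49 times the mean of random placement without regard to open chromatin (permutation of positions, p = 0.0010). Of the 224 that did meet one, 55 (24.6%) held a peak, more often (odds ratio 2.36, interval 1.49 to 3.71, Fisher exact test, p = 2.1e-04; within width quartiles 2.04, permutation p = 0.0029, a test chosen after this result was seen).

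The first pattern weighed is that 231-D-specific superenhancers coincide with MDA-MB-436 superenhancers more often than 231Pa-specific ones. Region width does not account for it, since 231-D-specific regions are narrower and the odds ratio within width quartiles was 4.92 (permutation p = 1.0e-05, the smallest possible). Within chromosomes it was 4.94 (permutation p = 1.0e-05), so the uneven chromosome distribution does not account for it either. 231Pa-specific regions were not placed without regard to enhancers, since they met MDA-MB-436 superenhancers 3.45 times as often as random placement (permutation of positions, p = 0.0010). A lower share of well-supported calls among the 231Pa-specific regions, or a state of the metastatic clone that is closer to MDA-MB-436, could each give the pattern, and neither was tested, because the lists carry no signal.

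The second pattern is the presence of NF-κB and cytokine genes at superenhancers of the OCT-2 cells alone. Neighbouring genes such as IL1A and IL1B share regions, but placing the 204 regions at random over gene ends gave a mean of 0.55 ± 0.75 list members and at most 5 in 1000 placements, against 6 observed (permutation of positions, p = 0.0010). A cut by width cannot tell whether the greater length of the OCT-2 list is the cause. The region lists carry no signal to rank regions, and the control list could not be lengthened. Among the 337 widest OCT-2 regions, of which 68.5% were shared, 4 of the 6 members of the NF-κB list stayed at a Luc+OCT-2-only region. Whether the list marks all superenhancers of these cells alike cannot be told apart from a link with OCT-2, since the odds ratio against shared regions was 4.19 (Fisher exact test, p = 0.066) on 9 genes. An effect of forced OCT-2, which the design names, may be involved and stays untested, since 4 of the 5 regions held an OCT-2 peak but so did 73.0% of all Luc+OCT-2-only regions.

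The third pattern is the uneven distribution of specific superenhancers over chromosomes in 231-D and 231Pa. A few clusters do not account for all of it, since counting regions within 1 Mb of one another once left a permutation p = 0.0057 (adjusted p = 0.040, against 0.0013 with all regions). Differences in chromosome copies between clone and parent are a candidate explanation: over the 23 chromosomes, the log2 ratio of 231-D-specific to 231Pa-specific regions rose with the log2 ratio of the shares of OCT-2 peaks in 231-D and 231Pa_Luc+OCT-2 (Spearman's rho 0.57, permutation p = 0.0063; Pearson's r 0.61, p = 0.0021). Without chromosomes 21 and 16, farthest from the median ratio of peak shares, r was 0.42 (p = 0.055) and rho 0.44 (p = 0.047). Peak shares only stand in for chromosome copies, which were not measured. The second set of peaks comes from cells with forced OCT-2, not from 231Pa. Of the 917 peaks of 231-D, 58 lay inside 231-D-specific regions, so both ratios draw in part on the same regions. A regulatory difference that acts on both superenhancers and OCT-2 binding stays open, and inputs could decide between it and chromosome copies.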

How the results depend on the processing

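Over 55 results, 176 alternatives were computed, 133 planned and 43 added after the lists had been seen; 146 kept direction and side of the threshold, or stayed within the interval, 12 values moved outside it, 10 calls became weaker, 5 stronger and 3 directions reversed. Depth, calling thresholds and replicate values are unknown. No paired analysis was possible because the lists were made from both replicates and carry no replicate values; for the same reason no replicate could be left out. Alternatives set beforehand on scores, the motif, genes of hg19 lists and gene-based placement in hg19 were not run.

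With only regions at or above the median width, the specific share was 37.0% in 231-D, 39.7% in 231Pa, 12.6% in MDA-MB-436_Luc2_No3a and 30.1% in 231Pa_Luc+OCT-2. These shares were lower than with all regions, since specific regions are narrower there. Except in 231Pa_Luc+OCT-2, the common regions they are set against are merged calls, widened by construction. In MDA-MB-436_Luc2 (22.7%) and 231Pa_Luc+GFP (8.04%) the share stayed within its interval. The shared part of the OCT-2 list was 53.7% with 50% reciprocal overlap, 53.7% with the wider regions of each list (at or above its median) and 68.5% with the 337 widest OCT-2 regions (added); that of the control list was 82.5%, 81.1% and 68.2%. Peaks within 3 kb of a gene end were 14.5%, a wider window by construction. The MDA-MB-436 ends at hg19 over hg38 ends were 31.0 to 1 within 100 bp, against 16.2 to 1 within 500 bp.

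For 231-D-specific against 231Pa-specific regions with a 231-D OCT-2 peak, the odds ratio became 2.14 within width quartiles, past the threshold. For Luc+OCT-2-only against shared regions it passed the threshold with peak centres (0.59, Fisher exact test, adjusted p = 0.049), regions extended by 10 kb (0.59), without the chromosome with most specific regions (0.51) and with 50% reciprocal overlap (0.57), but not within width quartiles (0.82). The cause was not tested beyond width. Directions reversed, none of them called, for the width of control-only against shared control regions (mean log2 difference -0.12), for OCT-2 peaks in the same pair with 10 kb extension (odds ratio 1.11) and for Luc+OCT-2-only against control-only regions within width quartiles (1.03). With the 337 widest OCT-2 regions (added), 1 gene list instead of 3 was called at Luc+OCT-2-only regions and 2 instead of 5 at shared ones; fewer regions were tested there. 231-D-specific against common regions in meeting MDA-MB-436 superenhancers gave an odds ratio of 0.66 with 50% reciprocal overlap (added), against 0.52 before, no longer past the threshold (Fisher exact test, p = 0.051). The cause of this change was not tested.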

Other observations

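OCT-2 peaks of 231Pa_Luc+OCT-2 clustered in some windows of 200 kb. The densest was part of the histone gene cluster on chromosome 6 (hg38, 26000001 to 26200000), with 9 peaks, of which 1 lay in a superenhancer. Neighbouring windows on chromosome 12 (75800001 to 76000000 and 76000001 to 76200000, the second with PHLDA1 and NAP1L1) held 8 and 7 peaks. SAMD4A, which also carries one of the widest superenhancers of the control cells alone, had 8 peaks in its window on chromosome 14, and neighbouring windows around TRERF1 on chromosome 6 held 7 and 8. The window with PIM1 and FGD2 held 7 peaks, none in a superenhancer. These windows were chosen by their peak number after it was seen, and were not tested.

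Of the 14 OCT-2 peaks at small nuclear RNA genes, 2 lay in superenhancers, and of the 17 at histone genes, 5 did.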
